A study of Homo sapiens with 6 samples.

How the data were processed

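Total RNA from sorted CD44-positive and CD44-negative COLO-320DM cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The 6 arrays were grouped by the CD44 status in their labels, 3 in each group. The deposited values are intensity values that RMA, a background correction, quantile normalization and probe set summary for Affymetrix arrays, had been applied to, per the submitters' processing notes. The version of RMA, the software that ran it and the genome build were not given in the sources used here. The design assumed values on the log2 scale. The deposited table held linear intensity values, so log2 was taken, as the design allowed, with no pseudocount. RMA makes the distributions of arrays alike and can compress differences near the background and near the top of the scale.

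The table held 54675 probe sets per array, 62 of them controls. A table of platform annotation named 1 gene for 41097 probe sets, several for 1801 and none for 11721. Of those with 1 gene, 41043 had a gene ID found in the RefSeq gene table, from which symbols were updated, and 54 kept the annotation's symbol. No gene was named from a probe set with several, and Y-linked genes and XIST were left out. Each of 19741 genes was represented by the probe set with the highest mean over the 6 arrays. Genes with a mean under the 30th percentile, 5.13 on the log2 scale, were left out as dim, which left 13819. No array was left out. Unnamed probe sets entered only a separate count.

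Genes were compared with limma 3.58.1 (lmFit and eBayes, in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CD44 and KIT were also tested by an exact permutation test over the 6 arrays, with every probe set of these genes read out. The permutation tests were enumerated in R. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Errors are the SD over 3 arrays for levels and limma's SE for differences, with 95% confidence intervals from the same fit.

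The labels share the numbers 01, 02 and 03 between the groups without stating a shared day or culture. The pairing therefore comes from the data. Deviations from the group means correlated between same-numbered arrays at 0.466, 0.690 and 0.627, and between arrays of other numbers from -0.497 to -0.107. The deviations of 3 arrays sum to 0, so the second range follows in part from the first. The pairing was read from the same arrays on which the block was then used. The numbers were taken to pair the arrays, and the fit with the replicate number as a block is printed beside a result where it changes a call or moves a count. The fit without the block had been set as the main design.

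The rule for named genes was set before the data were examined. Genes past the threshold without overlap between the groups were to be named, the 12 with the largest differences in each direction. Where fewer than 5 passed in a direction, the 6 with the smallest unadjusted p in it were named instead, as happened in both. CD44, KIT, KITLG, TNKS, TNKS2, AXIN1, AXIN2, APC, CTNNB1, MYC, LGR5 and PROM1 were named whatever their values. List members were to be named where they passed the threshold, up to 4 in a list. TNC, CMPK2 and LINC01234, which passed only with the block, and the members named in each list were chosen after their values were seen.

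The 34 gene lists were fixed before the data were examined, and each had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Members were also tested with adjustment over their list alone. That adjustment does not cover the 34 lists together, some of which share genes, so some of those calls may be due to chance. Camera with an estimated correlation and fry, a rotation test of whether the genes of a list move one way, were alternatives. With an estimated correlation and with fry no list was called, with or without the block. Median centring, another quantile normalization, no filter on dim genes, a limit at the 50th percentile, the mean of a gene's probe sets, only probe sets without the _s_at or _x_at suffix, every probe set, a variance trend with robust moderation, array weights and leaving out each array were the other alternatives.

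The gene and list tests were first run on simulated data for the 13819 genes with 3 arrays in each group, where 67 genes had been changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. Without the block 7.46% of the first, 92.5% of the second and 100% of the third set were recovered, with 1 false call. With the block these shares were 67.2%, 100% and 100%, with 8 false calls. A list of 29 genes shifted by 0.3 was recovered by camera in both fits and no other list was called. With an estimated correlation its adjusted p was 0.0344 without and 0.307 with the block, and with fry 0.0320 and 0.0543. The simulated genes varied independently of one another. In the real data the lists called without the block had estimated correlations from 0.124 to 0.306, against the preset 0.01. With the block those of the hypoxia and interferon lists were under the preset, at -0.0155 and -0.0158. Those of the HOX, TGF-beta and BMP, and fibroblast lists were 0.182, 0.248 and 0.324 with the block. The simulation therefore cannot show how often camera calls unshifted lists in these data.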

Results

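Gene expression was measured in COLO-320DM, a human colorectal cancer cell line known to carry amplified MYC, after the cells had been sorted by CD44. CD44 is a hyaluronan receptor that is widely used as a surface marker of colorectal cancer stem cells. The 6 arrays fell into 2 groups of 3, CD44-positive and CD44-negative, and the labels gave each group the replicate numbers 01, 02 and 03. No array came from treated cells. The median intensity of the arrays lay between 44.9 and 46.5, and the correlation of log2 values between arrays was 0.991 to 0.997. The number of arrays limited the precision of every value. The labels did not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Differences are given throughout as CD44-positive minus CD44-negative on the log2 scale.

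The first question was whether the sort marker itself separated the arrays. CD44 was 5.54-fold higher in the CD44-positive cells, at 7.70 ± 0.52 against 5.23 ± 0.22 (log2, SD, n = 3) on the probe set with the highest mean. It was higher in 3 of 3 pairs of same-numbered arrays, by 2.46, 2.83 and 2.12. The gene had 13 probe sets, of which 7 lay above the dim limit, and in all 7 every CD44-positive array exceeded every CD44-negative array. The differences of these 7 ranged from 2.06 to 5.12, but in 6 of them the CD44-negative mean lay under the dim limit of 5.13, so the size of these differences is approximate. The remaining 6 probe sets were dim on average. The two-sided exact permutation test gave p = 0.1 for the main probe set, the smallest value that 3 arrays against 3 can give. The difference of 2.47 ± 0.24 (SE) had an adjusted p of 0.107 without the replicate block and of 0.00173 with it. Without CD44-positive array 03 the unblocked difference was 2.76 with an adjusted p of 0.00433.

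The series concerns tankyrase inhibitors and the receptor tyrosine kinase c-KIT, so KIT and the genes of the tankyrase and Wnt pathway were read out whatever their values. KIT stood at 9.60 ± 0.66 in the CD44-positive and 8.93 ± 0.15 in the CD44-negative cells (log2, SD, n = 3), a difference of 0.67 ± 0.29 (SE) or 1.59-fold. The pairs differed in KIT by 1.17, 0.85 and -0.010, so that CD44-positive array 03, at 8.84, lay within the range of the CD44-negative arrays, 8.84 to 9.10. KIT did not pass the test, with an adjusted p of 1.00 without the block and 0.440 with it, and the exact permutation test (two-sided) gave p = 0.3. Without CD44-positive array 03 the difference was 1.05 (adjusted p = 0.154), and without pair 03 the blocked difference was 1.01 (adjusted p = 0.00165). In the other direction, it fell to 0.47 without CD44-positive array 01 and to 0.50 without CD44-positive array 02. Without pair 01 the blocked difference was 0.42. None of these 3 passed. KITLG, which encodes the KIT ligand, differed by -0.14, with a 95% confidence interval from -0.71 to 0.42.

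The tankyrases and the scaffold proteins they modify did not pass the test. TNKS differed by 0.0060 (95% interval -0.27 to 0.28), TNKS2 by -0.049 (-0.25 to 0.15) and AXIN1 by 0.040 (-0.18 to 0.26). AXIN2, a direct Wnt target as well as a scaffold of the destruction complex, was at a high level of 11.53 ± 0.19 against 11.57 ± 0.26, a difference of -0.042 (-0.40 to 0.31). APC differed by -0.14 (-0.35 to 0.070) and CTNNB1, the gene of beta-catenin, by -0.034 (-0.27 to 0.20). MYC stood at 14.04 ± 0.06 and 14.06 ± 0.04, close to the highest values of the arrays, 14.36 to 14.41. The stem cell gene LGR5 differed by -0.15 (-1.02 to 0.71). All of these genes had an adjusted p of 1.00, and the replicate block passed none of them. PROM1 was dim, with means of 3.21 and 3.06, and was not tested.

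With the same-numbered arrays taken as pairs (replicate block), 4 genes were higher and 4 lower in the CD44-positive cells. Beside CD44, the higher genes were TNC, the matrix glycoprotein tenascin-C, CMPK2, a mitochondrial nucleotide kinase inducible by interferon, and TCEA3, a transcription elongation factor. TNC was 3.55-fold higher, with a difference of 1.83 ± 0.15 (SE, adjusted p = 0.0191) and pair values of 2.31, 1.42 and 1.75. The groups overlapped in TNC, at 7.54 ± 0.85 against 5.71 ± 1.12 (log2, SD, n = 3), and its SE was 0.58 without the block. CMPK2 stood at 6.16 against 4.83, a difference of 1.34 ± 0.14 (adjusted p = 0.0440), and TCEA3 was 1.71-fold higher, by 0.77 ± 0.08 (adjusted p = 0.0440). The lower genes were SLITRK6, a neuronal transmembrane protein, at -1.31 ± 0.14 (adjusted p = 0.0440), and RLN2, which encodes the hormone relaxin, at 4.88 against 6.13, a difference of -1.25 ± 0.10 (adjusted p = 0.0191). The lower of the levels of CMPK2 and of RLN2 lay under the dim limit, so the size of both differences is approximate. MAOA, the gene of monoamine oxidase A, differed by -1.02 ± 0.11 (adjusted p = 0.0456), which is 2.02-fold lower, and the non-coding LINC01234 by -0.76 ± 0.08 (adjusted p = 0.0440). Each of the 8 kept its sign in 3 of 3 pairs. The RLN2 probe set carries the suffix for shared transcripts, and RLN1 is a close paralog, so this gene is uncertain.

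**Figure D1:**
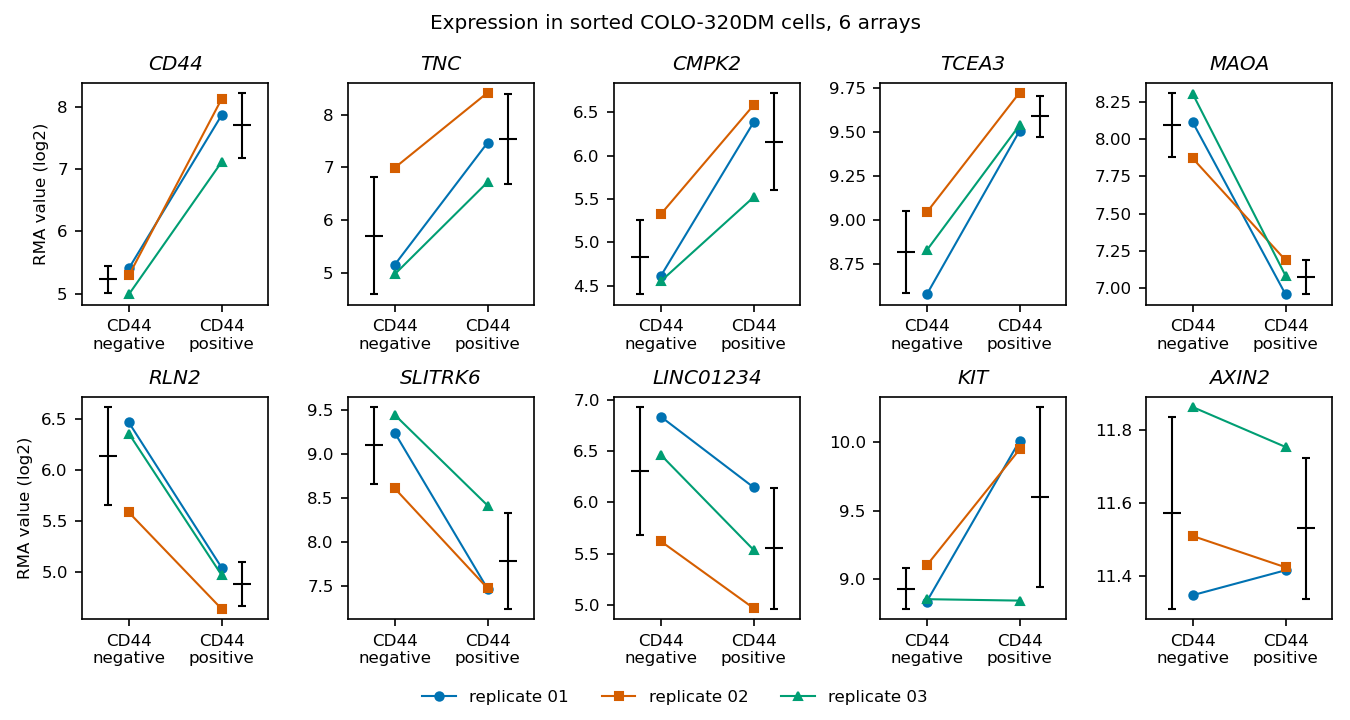
RMA values (log2) of 10 genes on each of the 6 arrays, with lines joining CD44-negative and CD44-positive arrays of the same replicate number and black marks for the mean ± SD of 3 arrays. CD44, TNC, CMPK2 and TCEA3 are higher and MAOA, RLN2, SLITRK6 and LINC01234 lower in all 3 pairs, while KIT is higher in pairs 01 and 02 only and AXIN2 has no common direction.

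Without the block no gene passed limma's test among the 13819 tested. At an unadjusted p under 0.05 there were 273 genes, 172 higher and 101 lower, against 691 by chance for unpaired arrays, and the smallest adjusted p was 0.107, for CD44. The block passed 8 genes, 6 of them at least 2-fold different, with 1038 at an unadjusted p under 0.05. In 750 genes (5.43%) the 2 groups did not overlap, against 10% by chance for unpaired arrays, a share that pairing lowers. The sign was the same in 3 of 3 pairs in 3941 genes (28.5%, against 25% by chance), and genes are not independent. The genes with the smallest unadjusted p in each direction were, beside those above, PLAAT3, a phospholipase, at 0.78 (adjusted p = 0.819), the neurofilament gene NEFL at 0.49, ANXA2 at 0.45 and the sorting nexin SNX7 at 0.83 (adjusted p = 1.00 each). On the other side CYP27C1, a cytochrome P450 that acts on retinoids, differed by -0.58, FRG1JP by -0.38 and PAPLN, the gene of papilin, by -0.36 (adjusted p = 1.00 each). These 7 genes did not pass with the block alone either, with adjusted p values from 0.0813 for PLAAT3 to 0.208 for PAPLN, though 5 of them, all but FRG1JP and PAPLN, passed with the block under another setting. With the mean of a gene's probe sets the difference of PLAAT3 shrank to 0.37 and that of PAPLN to -0.22. FRG1JP is a pseudogene of a multi-copy family and the ANXA2 probe set carries the cross-hybridisation suffix, so both are uncertain. The blocked count was 129 without pair 03, 66 without pair 02 and 10 without pair 01, and without pair 01 TCEA3 (adjusted p = 0.0595), LINC01234 (0.0631) and MAOA (0.0792) no longer passed. Quantile normalization ended the calls of CMPK2, LINC01234, MAOA and SLITRK6 (adjusted p = 0.0574 each), and testing dim genes as well ended these and that of TCEA3 (0.0599 each). With the mean of a gene's probe sets 3 of the 8 kept their calls, CD44, RLN2 and SLITRK6, while CMPK2 and MAOA (0.0554 each), TCEA3 (0.48, adjusted p = 0.0867) and LINC01234 (-0.52, adjusted p = 0.206) did not pass and TNC was not tested.

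Of the 34 gene lists, 4 were shifted towards higher values in the CD44-positive cells by camera and none towards lower values. The HOX genes, which encode developmental transcription factors, moved most, with a median difference of 0.24 over 21 tested members, 19 of them higher (adjusted p = 1.24e-06, but adjusted p = 0.960 with an estimated correlation). That 0.960 was shared by all 34 lists, so it does not rank them. Unadjusted, camera with an estimated correlation gave p = 0.0344 for the HOX, 0.0713 for the interferon, 0.154 for the TGF-beta and BMP and 0.359 for the hypoxia list. With the block these were 0.0927, 0.0563, 0.258 and 0.0600. HOXC9 stood at 7.08 against 6.35 and HOXC6 at 8.86 against 8.23, differences of 0.73 and 0.63. HOXD1 differed by 0.54 and HOXC10, with a dim CD44-negative level of 5.01, by 0.46. All 6 HOXC and all 7 HOXD genes tested were higher, with medians of 0.35 and 0.24, and 6 of 8 HOXB genes, with a median of 0.074. No HOX gene passed over all genes as planned or with the block alone. With the block, HOXC6 passed with a variance trend and with array weights, and HOXC6, HOXC9 and HOXD11 without pair 03. Adjusted over the list alone, 1 passed without the block, HOXC9, and 6 with it (HOXC9, HOXC6, HOXD1, HOXC10, HOXD11 and HOXB6). The list's median was 0.17, 0.41 and 0.090 in pairs 01, 02 and 03.

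Interferon response genes had a median of 0.11 over 19 members, 14 higher (adjusted p = 0.000938, but adjusted p = 0.960 with an estimated correlation). ISG15 differed by 0.45 and IRF1 by 0.34, and both passed with the block when adjusted over the list alone. The TGF-beta and BMP pathway had a median of 0.091 over 26 members, 19 higher (adjusted p = 0.00325, but adjusted p = 0.960 with an estimated correlation), and pair medians of 0.21, 0.084 and -0.0030. In this list TGFB1 was at 0.49 and the feedback inhibitor SMAD7 at 0.48, both passing with the block when adjusted over the list alone. GREM1, a BMP antagonist with a dim CD44-negative level of 4.79, differed by 0.85, with pair values of 0.96, 2.33 and -0.74. Hypoxia and glycolysis genes had a median of 0.075 over 28 members, 20 higher (adjusted p = 0.0442, but adjusted p = 0.960 with an estimated correlation), and none passed when adjusted over the list alone. PFKP stood at 0.33, ALDOC at 0.24 and BNIP3 at 0.20, while the stress-induced DDIT4 was at -0.40. No member of these 3 lists passed over all genes as planned or with the block alone. With the block, SMAD7 passed with a variance trend, with array weights and without pair 03, and TGFB1 with a variance trend and without pair 02. Without pair 03, ISG15, GREM1 and TGFB2 passed as well. The interferon call was lost without CD44-positive array 02 (adjusted p = 0.213) or CD44-negative array 01 (0.0797), and with only probe sets free of the _s_at and _x_at suffixes (0.564, with the block 0.555). The TGF-beta and BMP call was lost without CD44-positive array 01 (0.194) or 02 (0.0767), and the hypoxia call without CD44-positive arrays 01 (0.0573) or 02 (0.863) or CD44-negative array 03 (0.918). Without those suffixes the hypoxia call ended too (0.432, with the block 0.215). Only without the block, the TGF-beta and BMP call ended without those suffixes (0.0518, with the block 0.0285). The same held for the hypoxia call with no dim filter (0.0549, with the block 0.00742), at the 50th percentile (0.0824, with the block 0.0131) and with the mean of probe sets (0.0743, with the block 0.00582). With the block the TGF-beta and BMP call ended without pair 01 (0.140) and the hypoxia call without pair 02 (0.104) or 03 (0.123).

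Markers of other cell types were read in the same way. Fibroblast markers had a median of 0.10 over 12 members, 9 higher, with an adjusted p of 0.102 without the block and of 0.00674 with it, but adjusted p = 0.973 with the block and an estimated correlation. COL3A1 was at 11.09 against 10.31 and S100A4 at 6.99 against 6.28, and these 2 and COL1A2, at 5.40 against a dim 5.09, passed with the block when adjusted over the list alone. Over all genes, with the block, COL3A1 passed with median centring, at the 50th percentile and with every probe set. It also passed with a variance trend, with array weights and without pairs 02 or 03. S100A4 passed over all genes with a variance trend and without pair 02, both with the block. COL1A1 differed by -0.23. Without the block the list was called only when CD44-positive array 02 was left out (adjusted p = 0.0198), with the mean of probe sets (0.0423) or with every probe set (0.00665). The blocked call was lost without pair 01 (adjusted p = 0.0879), without _s_at and _x_at probe sets (0.215) and with array weights (0.103). Leukocyte markers had a median of -0.026 (adjusted p = 0.378) and were called as lower with every probe set only without the block (0.0228, with the block 0.0731). Markers of mast cells and blood progenitors had a median of 0.025 (0.904) and endothelial markers of 0.00098, with a mean of -0.019 (0.874). In RNA quality, GAPDH differed between its 3′ and 5′ probe sets by -0.081 ± 0.031 in the CD44-positive and -0.071 ± 0.010 in the CD44-negative arrays (log2, SD, n = 3), and ACTB by 0.010 ± 0.11 and 0.034 ± 0.043.

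The lists closest to the question of the series were not called in the planned fit or with the block alone, and no member of them passed over all genes in these fits. Wnt/beta-catenin target genes had 12 of 25 members higher, with a median of -0.012 and a mean of 0.031 (adjusted p = 0.933). The receptor gene FZD7 differed by 0.48 and SLC12A2 by 0.45, and both passed with the block when adjusted over the list alone. Over all genes, with the block, FZD7 passed with a variance trend and with array weights, and both genes without pair 03. The tankyrase and destruction complex list had 10 of 21 members higher, a median of -0.0044 and a mean of 0.010 (adjusted p = 0.904). Colorectal stem cell markers had 7 of 18 higher and a median of -0.099 (adjusted p = 0.378). Among these, adjusted over the list alone with the block, DCLK1 (0.62) and ALCAM (0.29) were higher and CD24 (-0.47), HOPX (-0.37) and TERT (-0.26) lower. Over all genes, with the block, DCLK1 passed with a variance trend, with array weights and without pair 03, and CD24 without pair 02. Without CD44-negative array 02 this list was called as lower (adjusted p = 0.0368). Receptor tyrosine kinases had a median of -0.019 and a mean of 0.022 (adjusted p = 0.904), with FGFR3 at 0.40 after KIT, and ERK pathway output genes a median of 0.033 (0.378). The ERK list was called as higher with the block and array weights (adjusted p = 0.0408, without the block 0.509), and its member SPRY2 passed over all genes with the block without pair 02.

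The differentiation and cell state lists were not called either. Mesenchymal genes had 12 of 20 higher and a median of 0.059 (adjusted p = 0.378, with the block 0.116). The blocked list was called without pair 01 (adjusted p = 0.0341) or 02 (0.0108) and with a variance trend (0.0338, without the block 0.373). With the block TNC passed over all genes, and S100A4 (0.71) and ACTA2 (0.44, against a dim 5.05) were higher and FN1 (-0.31) lower when adjusted over the list alone. Over all genes, with the block, ACTA2 and S100A4 passed without pair 02, and S100A4 with a variance trend as well. Epithelial genes had a median of -0.017 (adjusted p = 0.637), enterocyte and colonocyte genes 0.022 (0.479), goblet and secretory genes -0.0038 (0.904) and neuroendocrine markers 0.056 (0.637). KRT20, a keratin of mature colonocytes, differed by 0.63 and the neuronal enolase ENO2, dim in the CD44-negative cells at 4.93, by 0.49, each passing with the block when adjusted over its list alone. ENO2 passed over all genes with the block without pair 02. Genes of the extracellular matrix and integrins had a median of 0.013 (adjusted p = 0.941), and with the block COL1A2 was higher and FN1 lower when adjusted over the list alone.

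In the lists that follow no member passed over all genes in the planned fit or with the block alone, and no list was called in them. Calls of lists under another setting are given beside each list. Over all genes, with the block, LRATD2 passed without pair 02 and ASAP1, FAS and CYP1A1 without pair 03. S-phase genes had a median of -0.0019 and a mean of 0.0094 (adjusted p = 0.904), G2/M genes a median of -0.016 (0.706) and MYC targets with ribosome biogenesis -0.025 (0.479). The MYC target list was called as lower without CD44-negative array 03 (adjusted p = 0.0235). Genes of the 8q24 neighbourhood of MYC had a median of -0.010 and a mean of 0.049 (0.904), with LRATD2 at 0.58 and ASAP1 at 0.50 passing with the block when adjusted over the list alone. Notch pathway genes had a median of -0.0036 and a mean of 0.0042 (0.904) and Hedgehog genes a median of 0.077 (0.325). The 8q24 list was called as higher with every probe set only without the block (adjusted p = 0.0496, with the block 0.0551). The Hedgehog list was called as higher with every probe set (adjusted p = 0.0222, with the block 0.0148). Inflammatory NF-kB genes stood at -0.030 (0.904) and antigen presentation with MHC class II at 0.046 (0.325), the latter called as higher without CD44-positive array 01 (adjusted p = 0.0467) and with array weights (0.0312, with the block 0.103). Genes of p53 stood at 0.017 (0.836), with the death receptor FAS, dim in the CD44-negative cells at 4.96, at 0.47 passing with the block when adjusted over the list alone. The unfolded protein response was at -0.047 (0.378), called as lower with the block without pair 01 (adjusted p = 0.0240). Immediate early and heat shock genes were at -0.014 (0.904). Cholesterol and fatty acid synthesis was at 0.016 (0.619), and was called without CD44-positive array 02 (adjusted p = 0.0484). Oxidative phosphorylation was at -0.0097 (0.904). Drug efflux and detoxification had a median of -0.024 and a mean of 0.015 (0.904). Cancer-testis antigens had a median of -0.016 and a mean of 0.0088 (0.904), and PAGE1, at -0.39, was lower with the block when adjusted over the list alone.

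**Figure D2:**
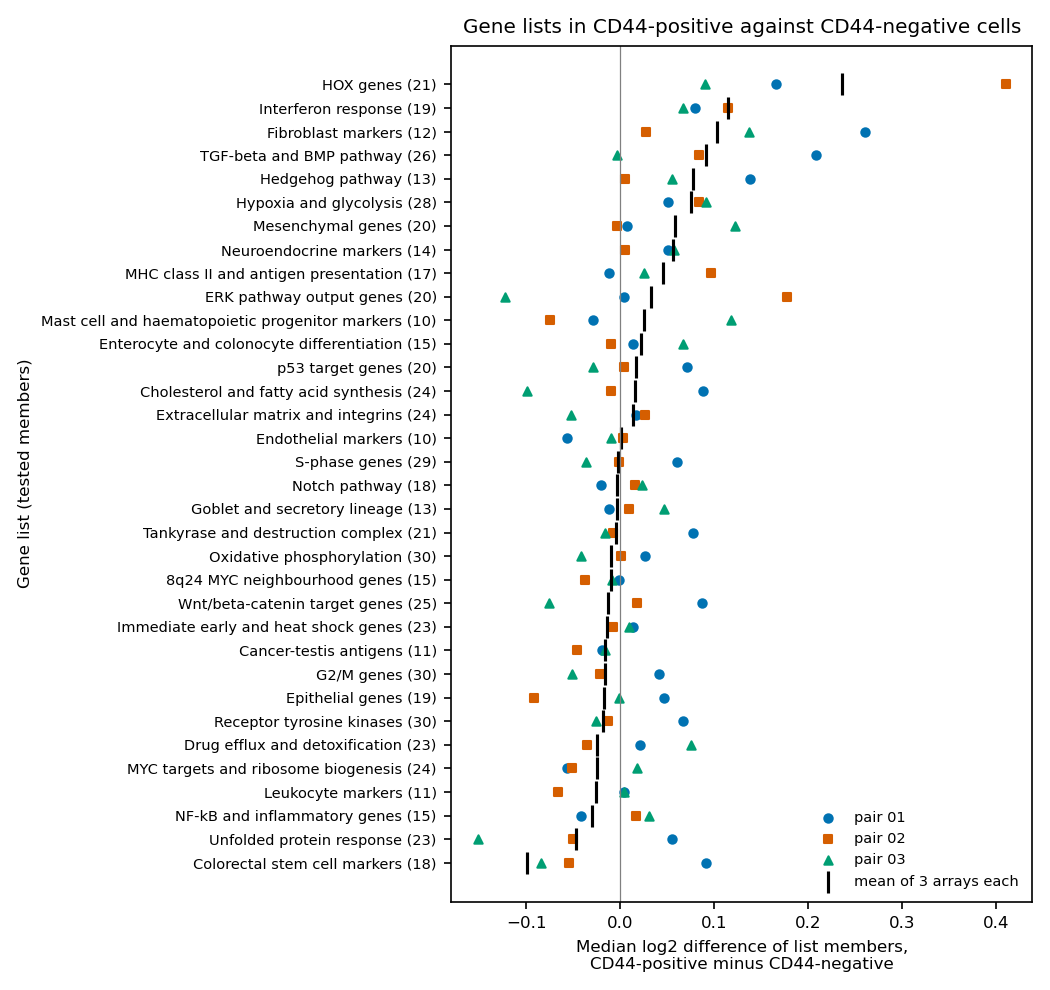
Median log2 difference, CD44-positive minus CD44-negative, of the tested members of each of 34 gene lists, with coloured points for the 3 pairs of same-numbered arrays and a black bar for the difference of the means of 3 arrays. The HOX genes have the highest bar, at 0.24, with all 3 pairs above 0, and the colorectal stem cell markers the lowest, at -0.099.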

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

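The count below was looked at after the main result had been seen. Among 4018 probe sets over the dim limit that have no gene named here and that enter no comparison above, 1 passed limma's test with the replicate block. It was higher in the CD44-positive cells by 1.21 on the log2 scale, with an adjusted p of 0.00184 over the unnamed probe sets alone. Without the block 0 passed. It drew attention as a difference in probe sets outside the tested genes, and no explanation for it was tested.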

How the results depend on the processing

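The alternatives that combine the replicate block with another setting, or leave out a pair, were chosen after seeing the data, and the others before. CD44 stayed higher in 16 of 16 alternatives, from 1.65 to 5.12, with adjusted p from 0.00173 to 1.00, and KIT in 15 of 15, from 0.47 to 1.05, with adjusted p from 0.154 to 1.00; KIT has no value without _s_at and _x_at probe sets, since its only probe set carries such a suffix. The count of genes was 0 as planned. It was 8 with the replicate block, 2 with no dim filter (CD44 and TNFSF10), 1 without _s_at and _x_at probe sets, 5 probe sets when each was tested (of CD44 and TNFSF10) and 1 with array weights, and 0 to 1 when 1 array was left out. The count at 2-fold was 6 with the block and 2, 1, 5, 1 and 0 to 1 in those settings. CD44 passed in these: 2.47 with the block (adjusted p = 0.00173), 2.47 with no dim filter (0.0372), 5.12 without _s_at and _x_at probe sets (0.00222), 2.47 among all probe sets (0.0461) and 2.66 with array weights (0.0141), and it ranged from 2.26 to 2.76 when 1 array was left out, passing without CD44-positive array 03 (0.00433). The block lowered its SE from 0.24 to 0.13. Camera called 4 lists, 1 without _s_at and _x_at probe sets, 8 with every probe set, and 0 with an estimated correlation or fry. With the block the gene count of 8 became 18 with median centring, 4 with quantile normalization, 5 with no dim filter, 16 at the 50th percentile, 20 without _s_at and _x_at probe sets, 33 probe sets when each was tested (of 20 genes), 75 with a variance trend, 43 with array weights, and 10 to 129 when 1 pair was left out (10 without pair 01, 66 without 02, 129 without 03). With the mean of probe sets it was 6, of which 3 were among the 8. All 8 genes were among those called with median centring, every probe set, a variance trend and array weights and without pairs 02 or 03. The blocked list count of 5 became 2 without _s_at and _x_at probe sets and 0 with an estimated correlation or fry. The HOX list was called in each of the 9 other settings of the data and variance model in both fits, without any 1 array and, with the block, without any 1 pair. In the planned setting the block changed the call of 1 list, the fibroblast markers, and of the 8 genes; under other settings it changed further list calls in both directions. No result turned its direction past the threshold. Of the values, 363 of 389 planned and 98 of 128 added ones kept their side of it or stayed within 1.5 times. Most planned ones belong to single named genes far from the threshold, which counted as kept even where their sign changed. Such shares therefore say little about the gene counts, the list count and CD44, which moved as given above. Fewer tested genes or arrays, or more, enter some of these settings. Otherwise the cause was not tested. Dim probe sets limit what can be read for genes such as PROM1.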

Other observations

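Of the tests in this part, those on CD44 separation and a wrong label behind KIT, on fibroblast RNA and on the neighbours of LINC00543 were chosen after the result was seen, as were the genes named in the next paragraph.

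Several genes outside the lists differed at least 2-fold with the same sign in 3 of 3 pairs without passing the threshold as planned or with the block alone. PDK4, a kinase that restrains pyruvate oxidation, stood at 6.97 ± 0.88 against 4.55 ± 1.53 (log2, SD, n = 3), a difference of 2.41 (blocked adjusted p = 0.0572). The sphingomyelin synthase gene SGMS2 differed by 1.70, ECHDC1 by 1.51, FUCA2 by 1.17, CASD1 by 1.17 and ENPP2, the gene of autotaxin, by 1.07. The cannabinoid receptor gene CNR1 differed by 1.06 (blocked adjusted p = 0.0521) and the chemokine receptor gene ACKR3 by -1.51 (0.236). Each of these genes passed with the block without pair 02, and several in further settings. PDK4 and CNR1 also passed with the block with median centring, without _s_at and _x_at probe sets and without pair 03. Neither was called with the block and quantile normalization, no dim filter or the mean of probe sets. PDK4, SGMS2 and CASD1 were dim in the CD44-negative and ACKR3 in the CD44-positive cells, so the size of these differences is approximate. In all, 16 genes differed at least 2-fold, 12 higher and 4 lower, and 15 of them kept their sign in 3 pairs. Among the 15 was LINC00543, whose difference in pair 02 was only 0.0097. ZIC2 differed in pair 02 alone, by 2.41.

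A pair of genes of cell death lay just under the dim limit of 5.13. TNFSF10, the gene of the death ligand TRAIL, stood at 5.78 ± 0.15 against 4.39 ± 0.22, a difference of 1.39 that passed without the filter (adjusted p = 0.0372, with the block 0.0207). MLKL, the effector of necroptosis, stood at 5.56 ± 0.22 against 4.55 ± 0.21, by 1.01 (0.410, with the block 0.0207). The CD44-negative levels of TNFSF10 and MLKL lay under the dim limit, so the size of both differences is approximate. PARP14, inducible by interferon and outside the fixed list, stood at 5.88 against a dim 5.12, by 0.77 in the same direction (blocked adjusted p = 0.0521). With the block PARP14 passed with median centring, every probe set, a variance trend and array weights. It also passed without _s_at and _x_at probe sets and without any 1 pair. It was not called with the block and quantile normalization, no dim filter or the mean of probe sets.

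KIT was higher in pairs 01 and 02 and not in pair 03. Less complete CD44 separation in pair 03 stays open. The linear CD44 difference of that pair kept a median of 0.530 of the mean of the other pairs over 7 bright probe sets (0.420 to 0.565). KIT kept -0.0066, but on 1 probe set in 1 pair, which cannot tell a reduced KIT difference from none. The limit of 0.4 was set after seeing the data, just under the lowest share, so the test decides nothing. A wrong label of CD44-positive array 03 is argued against by 7 of 7 bright CD44 probe sets in which it lay above all CD44-negative arrays. A near absence of contrast in all genes of pair 03 is argued against by 25 genes at least 0.7 apart in pairs 01 and 02. Their median share kept in pair 03 was 0.471 (0.288 to 0.640), against 0.955 for pair 01 (0.453 to 1.59) and 0.378 for pair 02 (0.323 to 0.576) in the same test. Differences across genes correlated at 0.295 between pairs 01 and 02, and at 0.196 and 0.173 between these and pair 03. A contrast that was only reduced in pair 03 therefore stays open. A difference in KIT between cultures may remain, which the labels do not allow to test, and a weaker sort in pair 03 may add to it or replace it.

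Of 21 HOX genes 19 had higher means in the CD44-positive cells, a list shift that camera called but not with an estimated correlation (adjusted p = 0.960), and 9 of 12 fibroblast markers did too (0.102, with the block 0.00674, and 0.973 with the block and an estimated correlation). The arrays came from a sorted cancer cell line and not from tissue, so fibroblast RNA would need a contamination that the labels do not name. The values do not exclude it. The test used 3 fibroblast transcripts over the dim limit. COL1A1 differed by -0.23, DCN by -0.036, the median, and COL1A2 by 0.31, so that they went both ways. DCN, at 5.65 against 5.69, and COL1A2, at 5.40 against 5.09, lay near the dim limit of 5.13, so the test cannot decide the question. It left out COL3A1, which was brighter than these and differed by 0.78, at 11.09 in the CD44-positive cells. COL3A1 was at 10.31 in the CD44-negative cells as well, and 11 of the 20 fibroblast genes listed lay over the dim limit there. Cells sorted as CD44-negative thus gave signal for these transcripts too, so they do not mark CD44-carrying fibroblasts alone. Of the 20 genes, 8 stand in another list. A sort by CD44 would not remove fibroblasts that carry it from the CD44-positive cells. Probe sets shared between genes are argued against by a median of 0.20 over the 16 HOX genes left without _s_at and _x_at probe sets. A shift in some pairs only stays open, since the lowest pair median was 0.090, between the limits set for it, and a biological difference by CD44 status is a hypothesis that this leaves open.

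AHR, the aryl hydrocarbon receptor, and its repressor gene AHRR differed by 0.52 and 0.69, and the target CYP1A1 by 0.47 (blocked adjusted p = 0.0634, 0.132 and 0.285). With the block, AHR passed at the 50th percentile, with a variance trend, with array weights and without pair 03. AHRR passed with a variance trend and without pairs 02 or 03, and CYP1A1 without pair 03. It was hypothesised that the receptor's output could be higher. The 8 other genes of a receptor list had a median of -0.037, with 3 higher and a one-directional fry p-value of 0.765 with the block, which argues against a rise of these 8 as a set. AHR, AHRR and CYP1A1 had been seen before and were left out, so a rise limited to such genes stays open.

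LINC00543 stood at 10.63, 5.13 and 8.77 in the CD44-positive arrays 01, 02 and 03 and at 4.32, 5.12 and 4.18 in the CD44-negative ones, on its single probe set. It did not pass as planned or with the block alone (blocked adjusted p = 0.383), though it did with the block without pair 02. Its CD44-negative mean of 4.54 lay under the dim limit of 5.13, so the size of the difference is approximate. LINC00543 lies beside CDX2, a transcription factor of the intestinal epithelium. A rise of the whole neighbourhood may have carried it, but the largest difference of the 4 tested neighbours in pairs 01 and 03 was -0.014, and CDX2 differed there by -0.21 and -0.065.

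The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split called 0 genes and the highest other 35. With a real count of 0 all 10 splits must give as many, so this comparison decides nothing. The split with 35 genes set CD44-positive 01 and 02 and CD44-negative 02 against the rest. It keeps pairs 02 and 03 whole. Every array correlated most with the same-numbered array of the other group, at 0.9955, 0.9965 and 0.9962 for 01, 02 and 03. The arrays were thus closer by replicate number than by CD44 status, and this structure may underlie the count. The other splits that part only 1 pair called 0 genes each. For lists the real split called 4 and the highest other 5, and 4 of the 10 splits gave as many. With the block, the 4 splits that part all 3 pairs are also too few for a share under 0.05. The real split called 8 genes and 5 lists and the highest others 2 genes and 3 lists, so that in each case 1 of 4 splits, the real one, gave as many. The others set arrays of different CD44 status together.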
